A study of Homo sapiens with 20 samples.

How the data were processed

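Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on primary human airway smooth muscle cells from 1 donor, with an antibody to the glucocorticoid receptor (GR, a ligand-activated transcription factor) or to RNA polymerase II (RNAPII). Cells received dexamethasone, a synthetic glucocorticoid, or its ethanol vehicle for 1 h. Some cultures had first been transduced for 17 h with an adenovirus carrying the transcription factor KLF15 (Ad-KLF15) or green fluorescent protein (Ad-GFP). Per the labels' protocols, cells were fixed with 1% formaldehyde for 5 min and libraries were read as 50-base single reads. The labels gave 18 ChIP libraries, 2 in each of 9 groups, and 2 input samples. The input samples were not analysed here.

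Each library had its own deposited peak list, so peaks were called per library and not on pooled replicates. Per the submitters' processing notes, CASAVA 1.4, Bowtie2 2 and SAMtools were used. The peak caller, its settings and the control library behind each list were not given in the sources used here. The same notes name the mouse build mm9. The lists hold chromosomes 20 to 22 and reach position 249240673 on chromosome 1, so their coordinates are not of the mouse genome. Positions are given as deposited, counted from 1, without a build name. The only reference at hand was a gene table of the GRCh38.p14 assembly, and no region was assigned to a gene. Chromosome Y was left out throughout.

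In each list the authors gave a score per peak, which equalled 10 times the −log10 p cut to a whole number, within 1, for all 1346865 peaks. Column 7 holds the authors' fold enrichment of the peak, a ratio to a background that is not named in the sources used here. Columns 8 and 9 hold the deposited −log10 p and −log10 q of the peak, with lowest values of 3.01 and 1.01. These values are the authors' own, and they were used only to describe, rank or filter peaks within a list. The number of reads behind each list is unknown, so no interval that needs depth is given, and a peak missing from a list can reflect fewer reads.

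A peak was taken as called at a −log10 q of 2 or more. For each comparison the called peaks of its 4 libraries were merged into regions wherever they shared at least 1 bp. A region was gained if it was called in both libraries of the first group and had no deposited peak in either library of the second, and lost in the reverse case. The same 4 libraries were also split in the other 2 ways, each in both directions, which gave 4 background counts. With only 3 possible splits the share of splits with a count as high is never under 1 in 3, so no p-value is attached to these counts. The regions named are those with the best place, taking the worse of their places by fold enrichment in the lists of the 2 replicates. Group definitions, the calling threshold, the region rules, these splits and the naming rule were chosen before the data were examined.

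Co-location was measured as the share of RNAPII regions with a GR region within 50 kb. Gained or lost RNAPII regions were compared with regions called in all 4 libraries by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 72 tests that included 10 kb and direct overlap. P-values under 1e-300 were set to that value. Regions are not independent replicates, so these p-values describe the lists and not the spread between cultures. This co-location was set up after the data had been seen, in place of a planned test around gene starts, because no annotation of the files' build was at hand.

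RNAPII domains were the called peaks of the 10 RNAPII libraries merged, with at least 400 bp covered in at least 2 libraries, which left 35221 domains. Domain length was the length covered by called peaks in a library, and change was the difference in mean log2(covered bp + 200) between groups. Domains were ranked by that change among those whose groups did not overlap. For 2 exchangeable libraries against 2, chance alone gives non-overlapping groups in at most 1 in 3 cases, both directions together. Ties, as where libraries have no coverage, lower this share, and differences in list length can shift it. The other splits were not counted for domains. The top 100 domains of one pair of groups were then examined in a pair with no library in common, again by Fisher's exact test (two-sided).

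This ranking was chosen after the data had been seen, and it stands in place of a model that was tried first. Planned limma tests on genes were not run because no annotation of the files' build was at hand. A limma 3.58.1 fit (R 4.3.3) of log2 covered length was then tried on the 35221 regions, with an adjusted p of 0.05 and under 19 settings in all. It was dropped once its counts had been seen. The counts moved strongly with the scaling and with single libraries, and centring shifts regions that have no coverage at all. Its counts and their ranges over these settings are given in the closing section and are not used as results. A fit with the replicate letter as a block was added later. Tests of gene lists and of the GR binding motif were also planned and not run, the latter because no genome sequence was used here.

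Alternatives were a −log10 q of 5 or more, peaks as deposited, absence of a called peak only, an overlap of 50% of the shorter interval, summits within 100 bp, and each library left out in turn. Equal numbers of peaks per library (90000 for GR and 30000 for RNAPII, by −log10 p), the 5000 peaks with the highest fold, direct overlap, and all alternatives for domains were added after seeing the data. With equal numbers, absence meant absence from the shortened list, so a deposited peak below the cut counted as absent. The region code was tested on simulated data, in which it recovered all 200 planted gained and all 200 planted lost regions in each of the 8 comparisons. Planted regions were always present in both libraries of their group and always absent from the other group. Their recovery thus checks the counting and not the sensitivity in real lists. With unchanged regions detected in 90% of libraries, the code also called 347 to 954 of these gained or lost by chance per comparison and direction. Replicates of the real lists overlapped less, by a mean of 81.6% for GR and 68.0% for RNAPII. The simulated counts can therefore understate the chance background of the real comparisons and are not used as one. The domain code recovered the direction of 100% of its top 100 domains when 200 of 20000 simulated domains in the dexamethasone comparison changed 8-fold. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.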

Results

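The peak lists of 18 ChIP-seq libraries from airway smooth muscle cells of 1 donor were compared to ask where dexamethasone and KLF15 change occupancy by GR and RNAPII. There were 4 GR groups (ethanol, dexamethasone, dexamethasone with Ad-GFP, dexamethasone with Ad-KLF15) and 5 RNAPII groups, which also included ethanol with Ad-KLF15. Each group had 2 libraries. The labels do not say that replicates came from separate cultures, so all spreads measure only the spread between these samples, which may be technical. The p-values printed are from Fisher's exact test over regions or domains. They describe the lists and do not measure the spread between libraries or cultures.

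GR lists held 100086 to 127262 called peaks per library and covered 42.8 to 63.5 Mb. RNAPII lists held 31087 to 53910 called peaks and covered 25.1 to 47.3 Mb. GR peaks were overlapped by peaks of another library in 81.6% of cases between replicates (range 80.7 to 82.3, 4 pairs) and in 68.9% between groups (range 57.5 to 80.2, 24 pairs). For RNAPII the mean was 68.0% between replicates (range 56.5 to 72.4, 5 pairs) and 59.0% between groups (range 50.1 to 70.2, 40 pairs). The lowest replicate pair was that of RNAPII with dexamethasone and Ad-GFP. Its replicate E had 31087 called peaks against 53088 in replicate C, and covered 25.1 against 46.1 Mb.

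**Figure D1:**
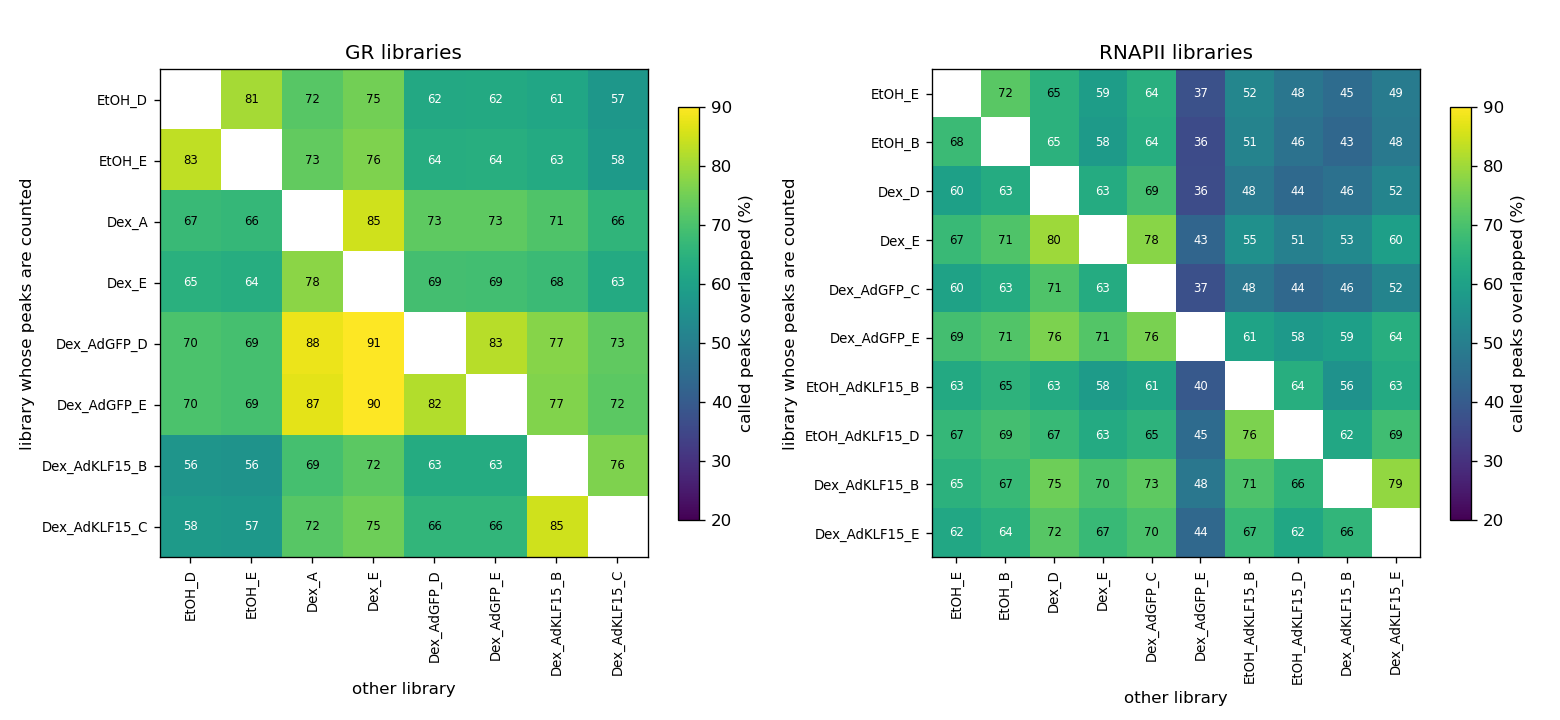
Percentage of the called peaks of each library (vertical axis) that were overlapped by a called peak of another library (horizontal axis), for GR (left) and RNAPII (right), with letters naming replicates. The column of RNAPII dexamethasone Ad-GFP replicate E is low throughout, and its partner had 37.1% of peaks overlapped by it.

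Dexamethasone was accompanied by more gained than lost GR regions. Of 167710 regions, 21700 were gained and 9043 were lost, while 64286 were called in all 4 libraries. The best-placed gained region was at chromosome 3, 156623701 to 156624864, where the authors' fold enrichment was 123 and 137 in the dexamethasone replicates and no ethanol library had a peak. Next came chromosome 10, 12288403 to 12290022 (folds of 110 and 139), and chromosome 11, 35929260 to 35930511 (98.7 and 107). Lost regions had lower folds, the best-placed being chromosome 11, 44876364 to 44877473 (16.4 and 15.0 in ethanol). Among the 1000 GR peaks with the highest fold in each dexamethasone library, 10.3% ± 0.28 (SD, n = 2) had no ethanol peak, whereas this held for 0.15% ± 0.21 (SD, n = 2) of the top ethanol peaks against dexamethasone.

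The other splits of the same 4 GR libraries gave 1302 to 2442 regions. With equal numbers of peaks per library, a setting added after seeing the data, 16681 were gained and 11694 lost, so the excess of gains was smaller. Deposited peaks below the cut count as absent in this setting, which relaxes the rule of absence. With 1 library left out the gained count was 25656 to 38414 and the lost count 13222 to 21087. Leaving a library out relaxes the rule, since 1 call or 1 absence fewer is then required. Libraries of other groups gave a further view of the same regions. Of the 21700 gained regions, 65.03% had a peak in both dexamethasone Ad-GFP libraries and 63.3% in both dexamethasone Ad-KLF15 libraries. For the 9043 lost regions these shares were 3.84% and 12.8%.

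**Figure D2:**
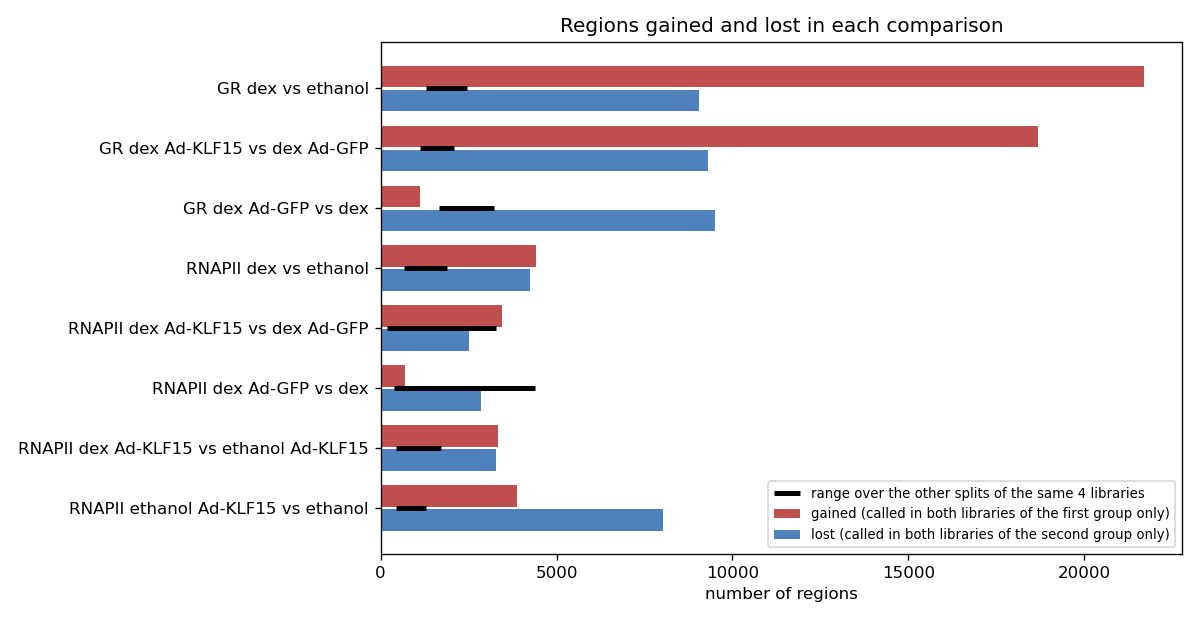
Number of regions (horizontal axis) gained (red) and lost (blue) in each of the 8 comparisons, with black lines for the range over the other splits of the same 4 libraries. Both GR comparisons of dexamethasone and of Ad-KLF15 lie above their black lines, whereas RNAPII dexamethasone Ad-GFP against dexamethasone lies within its own.

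Ad-KLF15 was accompanied by a changed set of GR regions in dexamethasone. Against Ad-GFP, 18702 of 158357 regions were gained and 9310 were lost, and 60177 were called in all 4 libraries. The best-placed gained regions were at chromosome 15, 52410918 to 52412169 (folds of 58.8 and 51.5), chromosome 2, 74786985 to 74788715 (63.9 and 42.8), and chromosome 10, 3450593 to 3451762 (46.0 and 41.2). The best-placed lost region was at chromosome 21, 36897668 to 36898119 (18.1 and 21.2 in Ad-GFP). Of the regions gained with Ad-KLF15, 14.2% had a peak in both dexamethasone libraries without virus and 64.0% in neither. Of the lost regions, 76.4% had a peak in both and 5.64% in neither.

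The other splits of these libraries gave 1114 to 2097 regions. With equal numbers of peaks the counts lay closer together, at 13707 gained and 11377 lost. Leaving out 1 library gave 23381 to 36828 gained and 12518 to 18642 lost regions under the relaxed rule. The regions with the highest folds were mostly common to both groups, as only 0.25% ± 0.071 (SD, n = 2) of the top 1000 GR peaks with Ad-KLF15 had no Ad-GFP peak.

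Transduction itself was examined by setting dexamethasone with Ad-GFP against dexamethasone alone. Here 1119 GR regions were gained and 9517 lost, with 1655 to 3227 in the other splits, so the gained count lay below them. With 1 library left out the counts were 2467 to 6116 gained and 16173 to 28816 lost. With equal numbers of peaks per library the order turned for gained regions: 2471 were gained and 3598 lost, and both lay above the 2052 to 2282 of the other splits. The 2 best-placed gained regions adjoined each other at chromosome 11, 5245998 to 5247498 (folds of 56.1 and 59.8) and 5247578 to 5247972 (22.3 and 21.2).

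RNAPII regions were gained and lost with dexamethasone in about equal number. Of 78445 regions, 4418 were gained, 4248 were lost and 21542 were called in all 4 libraries. The best-placed gained regions were at chromosome 11, 114049768 to 114052179 (folds of 15.4 and 16.0), chromosome 3, 126073738 to 126076685 (12.3 and 12.6), and chromosome 12, 32551801 to 32553556 (14.5 and 11.3). The best-placed lost region was at chromosome 1, 202508236 to 202509949 (6.53 and 6.80 in ethanol). Of the gained regions, 13.97% had a peak in both dexamethasone Ad-GFP libraries and 34.8% in both dexamethasone Ad-KLF15 libraries, against 63.6% and 75.1% of the regions called in all 4 libraries. The short list of Ad-GFP replicate E (31087 called peaks) limits the shares that need both Ad-GFP libraries. Neither library had a peak at 24.65% (Ad-GFP) and 43.2% (Ad-KLF15) of the gained regions. For lost regions, 2.73% and 5.96% had a peak in both and 69.96% and 83.6% in neither. In ethanol with Ad-KLF15, 15.9% of lost regions had a peak in both libraries and 64.95% in neither. Most thus lacked a peak there without dexamethasone too. For gained regions these shares in ethanol with Ad-KLF15 were 8.76% and 79.8%. The other splits gave 650 to 1887 regions. Leaving out 1 library gave 5685 to 16314 gained and 5548 to 15526 lost. At a −log10 q of 5 or more the counts were 2197 and 2030.

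In cells with Ad-KLF15, dexamethasone was accompanied by 3335 gained and 3292 lost RNAPII regions of 62636. The 2 best-placed gained regions, chromosome 3, 126074021 to 126076887 (folds of 11.4 and 11.8), and chromosome 11, 114049719 to 114052069 (10.9 and 10.2), lay at the positions of the leading regions of untransduced cells. Of the 3335 gained regions, 27.3% overlapped a region gained without virus, against 2.07% of regions called in all 4 libraries (odds ratio 17.8, Fisher's exact test, adjusted p at most 1.2e-299). Of the lost regions 8.87% overlapped a region lost without virus, against 1.41% (odds ratio 6.81, adjusted p = 3.98e-96). These comparisons share no library. Leaving out 1 library gave odds ratios of 8.85 to 13.6 for gained and 4.15 to 5.37 for lost regions. The other splits gave 432 to 1723 regions. Without 1 library the counts were 4114 to 11191 and 4275 to 14394, and at a −log10 q of 5 or more 1549 and 1304.

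Long RNAPII domains appeared with dexamethasone in both settings. The domain at chromosome 1, 116934563 to 116955687, had no called peak in ethanol, whereas 19.1 ± 1.4 kb were covered in dexamethasone. It was also uncovered in ethanol with Ad-KLF15, with 5.60 ± 1.9 kb in dexamethasone with Ad-KLF15. At chromosome 13, 110400425 to 110417987, the covered length was 14.5 ± 1.7 kb with dexamethasone and 0 without, and 5.43 ± 0.75 kb against 0.133 ± 0.19 kb in Ad-KLF15 cells. The domain at chromosome 1, 169429331 to 169443232, had 10.8 ± 0.35 against 0.135 ± 0.19 kb, and 5.72 ± 1.2 kb against 0 with Ad-KLF15. The most shortened domain, chromosome 15, 81071492 to 81102492, had 29.1 ± 2.1 kb in ethanol and 0.697 ± 0.28 kb in dexamethasone, but with Ad-KLF15 it was already short in ethanol (1.19 ± 0.68 kb, and 0.178 ± 0.25 kb in dexamethasone). These domains lead the ranking in their direction, and values are means ± SD of 2 libraries.

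Of 35221 domains, 20.7% were longer and 26.3% shorter with dexamethasone without overlap between the groups. For exchangeable libraries chance gives at most 1 in 3 for both together. Differences in list length can shift this share and the other splits were not counted, so no excess is read from it. Of the top 100 longer domains, 81% were also longer with dexamethasone in the separate Ad-KLF15 libraries, against 21.3% of the other domains (Fisher's exact test, p = 6.99e-37). A domain with no called peak in ethanol with Ad-KLF15, such as chromosome 17, 62606550 to 62613640, cannot count as shorter in those libraries. Of the top 100 shorter domains, 2 were longer there and 27% were also shorter, against 15.6% (Fisher's exact test, p = 0.00335). By the same exact test the latter was not past 0.05 at a −log10 q of 5 or more (18%, p = 0.397), nor without ethanol replicate B (22%, p = 0.0957), dexamethasone Ad-KLF15 replicate B (27%, p = 0.0751) or dexamethasone Ad-KLF15 replicate E (27%, p = 1.0).

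**Figure D3:**
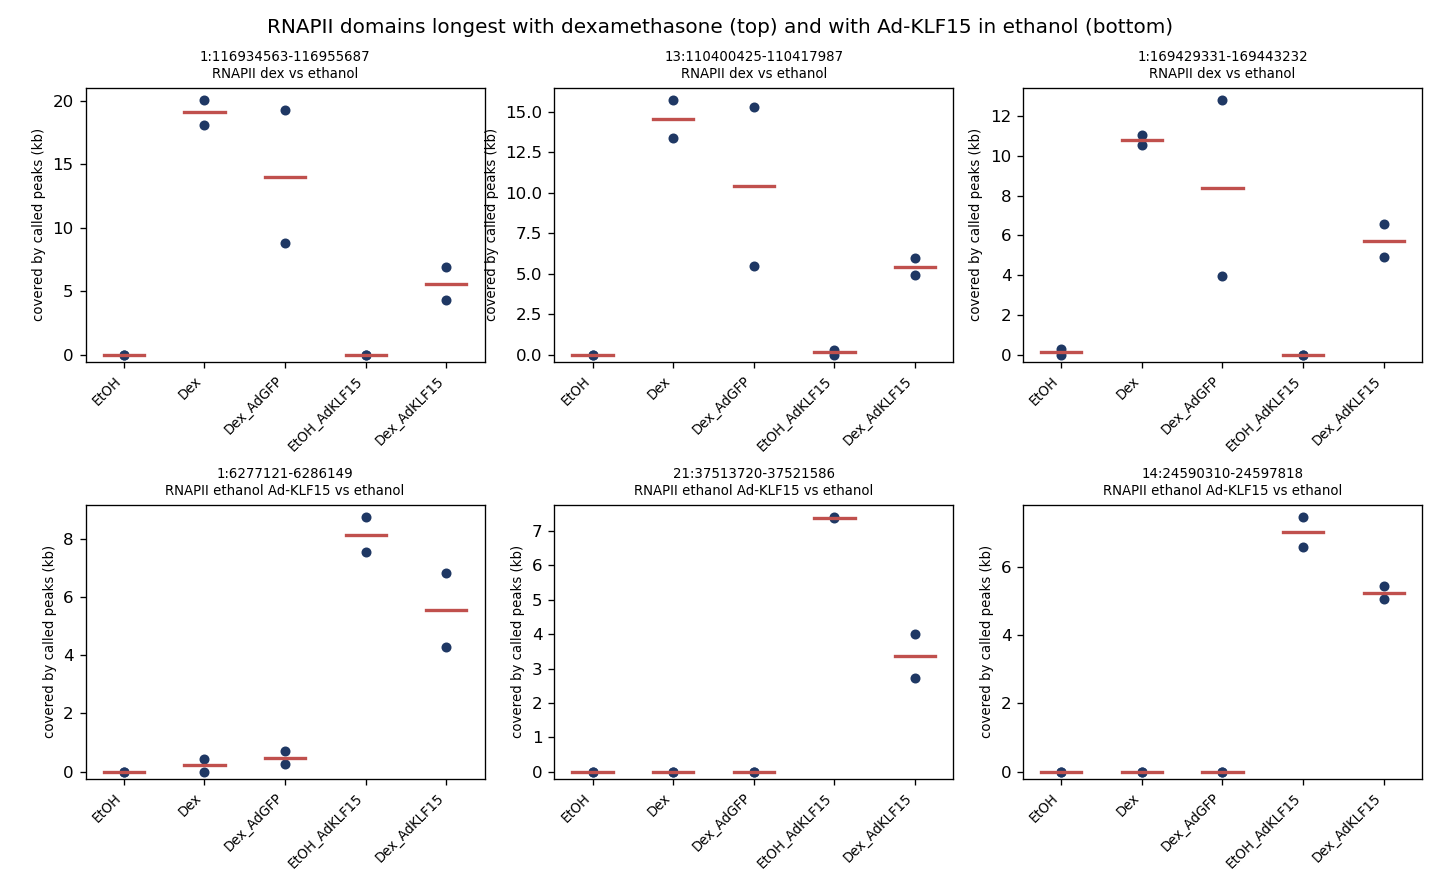
Length covered by called RNAPII peaks (vertical axis, kb) in each library (points, with red lines for the means of 2) at the domains most lengthened by dexamethasone (top) and by Ad-KLF15 in ethanol (bottom), for the 5 RNAPII groups. The domain starting at 116934563 on chromosome 1 has no coverage in either ethanol group, and a mean of 19.1 kb in dexamethasone.

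Ad-KLF15 was accompanied by RNAPII domains that were short or uncovered in the other groups. At chromosome 6, 29554376 to 29577204, the covered length was 20.95 ± 0.86 kb in ethanol and 16.0 ± 0.83 kb in dexamethasone with Ad-KLF15, and 1.51 ± 0.074, 0.269 ± 0.011 and 0 kb in ethanol, dexamethasone and dexamethasone with Ad-GFP. The domain with the next largest change against Ad-GFP, chromosome 1, 23682568 to 23691783, had 8.695 ± 0.0997 kb in dexamethasone with Ad-KLF15, 0.3725 ± 0.111 kb in ethanol with Ad-KLF15, and 0 in the remaining groups. At chromosome 16, 66877102 to 66886284, it was 6.16 ± 1.3 and 8.37 ± 0.35 kb with Ad-KLF15 and 0 in the remaining groups. At chromosome 14, 24590310 to 24597818, which like the last is among the 10 most lengthened in both settings, it was 7.003 ± 0.62 and 5.23 ± 0.27 kb with Ad-KLF15 and 0 in the remaining groups. The domain at chromosome 17, 642735 to 649537, went the other way, from 5.17 ± 0.90 kb with Ad-GFP to 0 with Ad-KLF15 in dexamethasone. All are means ± SD of 2 libraries.

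The top 100 domains longer in ethanol with Ad-KLF15 than in ethanol were also longer with Ad-KLF15 than with Ad-GFP in dexamethasone in 92% of cases, against 17.8% of other domains (Fisher's exact test, p = 8.12e-59). For the top 100 shorter domains the share was 39% against 12.7% (Fisher's exact test, p = 3.49e-11). Without dexamethasone Ad-GFP replicate E the share was 90%. Leaving that library out relaxes the rule of non-overlapping groups. The share of other domains under this setting is not given here, so the 90% cannot be set against the 12.7%. No ethanol library with Ad-GFP was analysed here, so in ethanol KLF15 cannot be told apart from transduction.

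By presence of peaks, 3865 RNAPII regions were gained and 8020 lost in ethanol with Ad-KLF15 against ethanol, with 448 to 1301 in the other splits. Leaving out 1 library gave 4693 to 13490 and 9387 to 22967. A −log10 q of 5 or more gave 1964 and 4475, and equal numbers of peaks 3105 and 3801, so the excess of losses was smaller. The best-placed gained region was chromosome 11, 5245946 to 5248027 (folds of 109 and 115), at the position already named for GR with Ad-GFP. The next were chromosome 3, 126070482 to 126071986 (24.2 and 21.7), and chromosome 19, 36359012 to 36360817 (16.7 and 14.9).

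In dexamethasone, Ad-KLF15 against Ad-GFP gave 3464 gained and 2498 lost RNAPII regions. The best-placed gained regions were chromosome 16, 8767712 to 8769733 (folds of 14.1 and 16.3), and chromosome 12, 53599421 to 53607248 (14.6 and 12.4). The other splits gave 182 to 3292, so the gained count lay just above them and the lost count within. With equal numbers of peaks, 3199 were gained and 1547 lost, with 285 to 1583 in the other splits. Under the relaxed rule of 1 library left out, gained regions numbered 11080, 9133 and 10117 without Ad-KLF15 replicate B, Ad-KLF15 replicate E and Ad-GFP replicate C, and 3752 without Ad-GFP replicate E. Lost regions numbered 10048 without Ad-GFP replicate C and 23185 without Ad-GFP replicate E, and 632 at a −log10 q of 5 or more (gained 1580).

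For RNAPII with dexamethasone and Ad-GFP against dexamethasone alone, 706 regions were gained and 2846 lost, and both counts lay within the 371 to 4400 of the other splits. With equal numbers of peaks, 565 were gained and 1771 lost, with 304 to 1566 in the other splits, so the lost count lay above them. With 1 library left out they were 1041 to 12299 and 3297 to 14863, the highest gained count being without Ad-GFP replicate E and the highest lost count without Ad-GFP replicate C. At a −log10 q of 5 or more they were 79 and 1048.

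RNAPII regions gained with dexamethasone lay near GR regions gained with dexamethasone. Within 50 kb of such a GR region lay 83.0% of gained, 67.4% of lost and 66.6% of constantly called RNAPII regions (gained against constant, odds ratio 2.44, Fisher's exact test, adjusted p = 4.68e-111). Within 10 kb the shares were 47.5%, 23.9% and 27.8%, and for direct overlap 10.7%, 1.08% and 4.39%. For dexamethasone in Ad-KLF15 cells the shares within 50 kb were 86.7% of gained and 65.03% of constant regions (odds ratio 3.51, adjusted p = 3.06e-152). GR regions lost with dexamethasone were near 54.6% of lost and 40.7% of constant RNAPII regions (odds ratio 1.76, Fisher's exact test, adjusted p = 4.05e-62). By direct overlap the order turned, with 1.48% and 4.40% (odds ratio 0.327, Fisher's exact test, adjusted p = 4.14e-23). Constant regions were wider, however, with a median of 1441 against 594.5 bp. Against gained RNAPII regions (median 583 bp) lost ones still overlapped more often, 1.48% against 0.385% (odds ratio 3.90, Fisher's exact test, adjusted p = 6.07e-08). Leaving out 1 library gave odds ratios of 1.76 to 2.93 without virus and 2.32 to 4.96 with Ad-KLF15.

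RNAPII regions gained with Ad-KLF15 lay near GR regions gained with Ad-KLF15. Within 50 kb the share was 78.8% of gained against 58.6% of constant regions in dexamethasone (odds ratio 2.63, Fisher's exact test, adjusted p = 1.17e-112), and 79.5% against 61.0% in ethanol (odds ratio 2.48, adjusted p = 1.27e-111). By direct overlap in dexamethasone the order turned, with 10.9% of gained and 13.3% of constant regions (odds ratio 0.799, adjusted p = 0.000192), whereas in ethanol it did not, with 14.3% and 10.8% (odds ratio 1.375, Fisher's exact test, adjusted p = 2.33e-09). Constant regions were wider than gained ones in both settings, so direct overlap does not compare regions of like width. Median widths were 1762 against 582.5 bp in dexamethasone and 1486 against 528 bp in ethanol. Whether width accounts for the turned order in dexamethasone was not tested. Of the lost regions in dexamethasone, 0.64% overlapped directly (gained against lost, odds ratio 18.9).

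**Figure D4:**
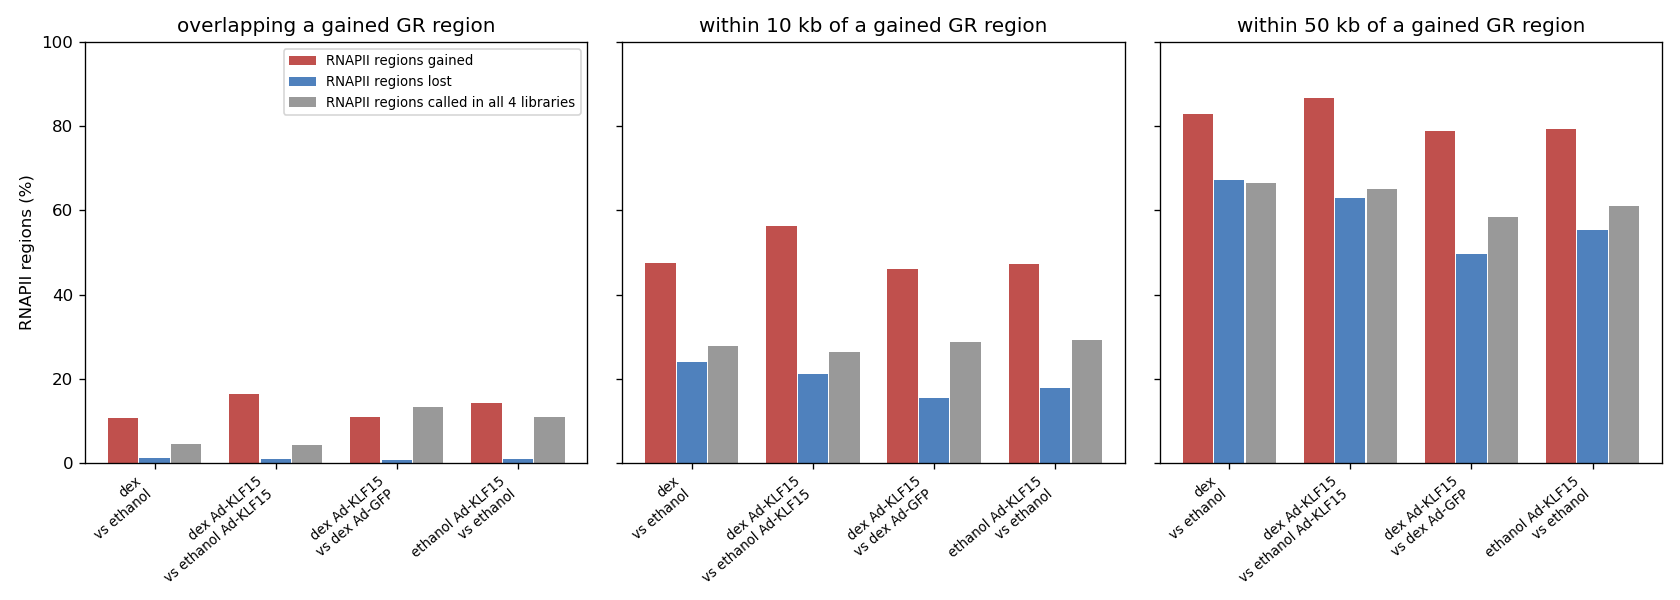
Percentage of RNAPII regions (vertical axis) that overlap, or lie within 10 kb or 50 kb of, a GR region gained with dexamethasone (the 2 left groups of bars in each panel) or with Ad-KLF15 (the 2 right groups), for RNAPII regions gained, lost and called in all 4 libraries. Gained RNAPII regions have the highest share within 10 kb and within 50 kb, with 47.5% and 83.0% for dexamethasone without virus.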

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

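All tests weighed below, their bounds, and the regions given as examples were chosen after the results they bear on had been seen.

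Some RNAPII regions had opposite patterns of called peaks under dexamethasone with and without Ad-KLF15. Of the 3292 regions lost with it in Ad-KLF15 cells, 21 (0.638%) overlapped a region gained without virus, such as chromosome 6, 130341232 to 130341566, against 2.07% of constantly called regions. Of the 3335 gained ones, 12 (0.36%) overlapped a lost region, such as chromosome 18, 67455125 to 67455601, against 1.41%. In 18 and 10 of them, each of the 4 libraries concerned had a peak at the region, which is what singled them out. The weakest peak of each stood at place 19441 to 53497 of its list. The difference at single regions was not tested, and chance presence of weak peaks was not excluded.

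The GR regions gained with Ad-KLF15 are the first pattern weighed. Longer peak lists in the Ad-KLF15 libraries are argued against, since with equal numbers of peaks per library the gained count was still 10.4 times the highest other split. Weaker enrichment in the Ad-GFP libraries would leave the regions present in untransduced cells, yet 14.2% had a peak in both dexamethasone libraries without virus and 64.0% in neither, which argues against it as the whole cause and leaves it open for the others. A change of these cells with Ad-KLF15 may account for it: in ethanol, in libraries separate from the GR ones, RNAPII regions gained with Ad-KLF15 had such a GR region within 10 kb more often than lost ones (odds ratio 4.18). A culture or library batch that follows the groups was not tested, and unspecific capture of active regions by the GR antibody remains open too. Of the gained regions, 10.92% overlapped RNAPII regions constantly called without virus (20.3% of the wider GR regions called in all 4 libraries). This share cannot decide it, since a gained region must lack a peak in both Ad-GFP libraries. Regions already active there would be captured in them too. Of RNAPII regions gained with Ad-KLF15 in ethanol, 14.3% overlapped an Ad-KLF15-gained GR region, against 0.773% of lost ones, which such capture would also give.

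The region at chromosome 11, 5245921 to 5248048, was called in all 10 libraries with a virus and both antibodies. It ranked first by fold in 5 of 6 such RNAPII libraries (folds of 41.3 to 115), while of the 8 libraries without virus only the 2 RNAPII dexamethasone ones had a peak there (5.27 and 7.09). Sequence carried by the viral vectors may be the source. Over the 10 libraries with a virus, the outer peak edges differed by at most 83 bp. No other RNAPII peak of these libraries lay within 20 kb on either side. The empty flanks and a place within the first 1659 of the 4 GR lists with a virus go against transcription of the cells' own copy but do not exclude it, since of the 1000 highest RNAPII peaks of each untransduced library 1 to 3 showed both. The sequence of the vectors was not used here.

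The RNAPII list of dexamethasone Ad-GFP replicate E stood apart from the others. Labels exchanged with a library of an unlike RNAPII group would leave a second pair out of place, but replicates of the other 4 groups overlapped by at least 69.95% (56.5% here). This cannot decide on an exchange with untransduced dexamethasone, since replicate C overlapped those libraries as replicates do, by 69.9% and 70.2%. A shorter list of the same kind of peaks is argued against by its overlap with GR lists, 34.1%, where the other libraries reduced to 31087 peaks gave at least 55.1%. A single wrong label within the series is argued against too: the region of the virus libraries had a fold of 41.3, and regions gained with Ad-KLF15 in ethanol had a peak here 0.446 times as often as lost ones (4.09 and 4.34 in dexamethasone with Ad-KLF15, at equal numbers of peaks), although this also lay above the 0.208 to 0.273 of the Ad-GFP partner and the untransduced dexamethasone libraries. Of its own called peaks, 75.85% were overlapped by its partner and 76.2% and 71.2% by the untransduced dexamethasone libraries. The shares were 69.0% and 70.9% for ethanol libraries and 57.8 to 63.8% for RNAPII libraries with Ad-KLF15. Most of its peaks were thus also in the other RNAPII lists. A lower quality of this library, or a sample from outside the series, may remain as explanations and were not tested.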

How the results depend on the processing

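Equal numbers of peaks, direct overlap, the 5000 highest peaks, and every setting for domains, shared regions and the limma fit were chosen after seeing the data. Of 152 values for 30 results under alternatives other than leaving out a library, 124 kept their call or stayed within 1.5 times, 26 moved, 1 lost its call and 1 reversed. Depth is unknown and limits all absences of peaks. Groups compared share at most 1 replicate letter, so region counts, which come from no test, were not paired. Planned gene, gene list and motif results were not run. The causes of the changes were not tested, except that stricter thresholds and equal lists hold fewer peaks. Under equal lists, absence is also easier to meet, since it is absence from the shortened list.

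At a −log10 q of 5 or more, gained and lost counts were 693 gained for GR with Ad-GFP against dexamethasone, and for RNAPII 2197 and 2030 (dexamethasone), 1580 and 632 (Ad-KLF15 against Ad-GFP), 79 and 1048 (Ad-GFP against none), 1549 and 1304 (dexamethasone in Ad-KLF15 cells), and 1964 and 4475 (Ad-KLF15 in ethanol). Summits within 100 bp gave 3069 gained for GR with Ad-GFP and 1471 and 4705 for RNAPII with Ad-GFP. Equal lists gave 2471 and 3598 for GR with Ad-GFP, 2681 and 2226 for RNAPII with dexamethasone, and losses of 1547, 1771, 2058 and 3801 for the other RNAPII comparisons in the order above. The gap in GR overlap within and between groups, 12.7 points, was 13.4 points at a −log10 q of 5 or more and 35.7 for the 5000 highest peaks. The top 100 domains shorter with dexamethasone fell to 18% at a −log10 q of 5 or more. The odds ratio of RNAPII and GR regions gained with Ad-KLF15 in dexamethasone reversed to 0.799 with direct overlap. In ethanol it was 1.375. Constant regions were wider than gained ones in both settings, and the part of width was not tested.

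Leaving out 1 library gave these ranges of gained and lost counts: for GR, 25656 to 38414 and 13222 to 21087 (dexamethasone), 23381 to 36828 and 12518 to 18642 (Ad-KLF15), 2467 to 6116 and 16173 to 28816 (Ad-GFP). For RNAPII they were 5685 to 16314 and 5548 to 15526 (dexamethasone), 3752 to 11080 and 2936 to 23185 (Ad-KLF15 against Ad-GFP), 1041 to 12299 and 3297 to 14863 (Ad-GFP), 4114 to 11191 and 4275 to 14394 (dexamethasone in Ad-KLF15 cells), 4693 to 13490 and 9387 to 22967 (Ad-KLF15 in ethanol). Odds ratios ran from 1.76 to 2.93, 2.32 to 4.96, 1.79 to 2.99 and 2.04 to 2.65 for RNAPII near GR regions, and from 8.85 to 13.6 and 4.15 to 5.37 for regions gained or lost both with and without Ad-KLF15. Overlap gaps ran from 11.1 to 14.1 (GR) and 8.00 to 12.7 points (RNAPII). Domain shares ran from 75 to 90% and 22 to 43% (dexamethasone, longer and shorter) and 87 to 95% and 34 to 90% (Ad-KLF15).

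The limma fit on RNAPII region length, tried under 19 settings and dropped after its counts were seen, called 971 regions wider and 1334 narrower with dexamethasone. Over the 18 alternatives this ran from 112 to 2664 and 19 to 2135, and the split turned between 574 and 1163 without centring and 1140 and 358 with centring on the median. In the same order it called 1956 (178 to 6300) and 1180 (358 to 3278) for Ad-KLF15 against Ad-GFP, 0 (0 to 463) and 0 (0 to 6036) for Ad-GFP against none, 635 (98 to 1998) and 416 (19 to 1300) for dexamethasone in Ad-KLF15 cells, and 2603 (838 to 3419) and 3263 (465 to 5541) for Ad-KLF15 in ethanol. The difference between dexamethasone effects with and without Ad-KLF15 gave 13 and 13, with 0 to 1293 and 0 to 995. Of 216 alternative counts over its 12 results, 99 moved by over 1.5 times. The domain ranking used in its place was itself chosen after these counts were seen. With the replicate letter as a block, added later and leaving 2 residual degrees of freedom, the fit called 95 and 28 with dexamethasone, 2348 and 646 (Ad-KLF15 against Ad-GFP), 18 and 642 (Ad-GFP), 119 and 25 (dexamethasone in Ad-KLF15 cells), 1988 and 2810 (Ad-KLF15 in ethanol), and 0 and 0 for the difference. Deviations of libraries with the same letter from their group means correlated by −0.0152 to 0.0675 over 10 pairs.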

Other observations

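The counts of regions common to all libraries of a treatment, their tests, and the regions given as examples were chosen after the data had been seen. In 18 regions a peak was called in all 12 dexamethasone libraries of both antibodies and none was deposited in any of the 6 ethanol libraries. Among them were chromosome 3, 156319031 to 156322231 (GR folds of 68.4 to 80.0), chromosome 10, 79628962 to 79630633 (69.1 to 102), and chromosome 5, 171852395 to 171854533 (60.9 to 76.1). Their RNAPII folds were low, at 3.94 to 8.90, 3.056 to 6.495 and 4.19 to 10.15. Some regions also had lower GR folds, such as chromosome 16, 1595167 to 1596189 (5.165 to 12.74). Only 1 of 40 choices of as many GR and RNAPII groups, the real one, gave as many, and the highest other gave 5. Other choices can join GR and RNAPII groups of unlike treatments, so these counts alone do not exclude chance. The count was 121 without RNAPII dexamethasone Ad-GFP replicate E, and 3 at a −log10 q of 5 or more. The reverse, a peak in all 6 ethanol libraries and none in the 12 with dexamethasone, held in 2 regions; 4 of 40 choices gave as many, so chance cannot be excluded, and the highest other, the Ad-KLF15 groups described next, gave 78.

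In 78 regions a peak was called in all 6 Ad-KLF15 libraries and in none of the other 12. They included chromosome 1, 16285480 to 16286808 (GR folds of 13.8 to 18.2), and chromosome 1, 21658174 to 21659890 (18.1 to 22.4). Their RNAPII folds were 4.24 to 5.43 and 3.98 to 5.12. Some regions had lower GR folds, such as chromosome 20, 44650654 to 44651985 (3.04 to 3.78). Here too 1 of 40 choices, the real one, gave as many, and the highest other gave 3, with the same limit on what such choices can exclude. The count was 118 without RNAPII dexamethasone Ad-KLF15 replicate B, and 35 at a −log10 q of 5 or more. A batch of cultures that follows the Ad-KLF15 groups cannot be told apart from the virus.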
